A study of Homo sapiens with 7 samples.

How the data were processed

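Small RNA of LNZ308 cells (10 µg per sample) was treated with the demethylase AlkB and a mutant of it, which removes methyl groups that block reverse transcription, per the labels' protocols. Input libraries were prepared from this RNA. For cleaved libraries the RNA was reduced with 0.1 M NaBH4 and cut with aniline at m7G. The knockdown cells were stable clones selected with puromycin at 2.5 µg/mL, per the labels' protocols, so a difference between clones goes with the group.

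The submitters' processing notes name Trim Galore, Bowtie, bedtools and the genome build hg19, with no versions. The annotation and the treatment of reads that match several gene copies are not given in the sources used here. Names of 2 genes carry a contig name of a later build, so no coordinates are printed, and chromosomes are as the gene names give them. The authors deposited abundance as RPM per tRNA gene and library, each library summing to just under 1000000. The deposited values were whole multiples of 1 step in 100% of values per library at a tolerance of 0.001. Copies with identical sequence appear to be counted in each copy: 244 of 536 genes share all 4 values with another gene, which leaves 355 distinct profiles. The implied totals are therefore alignments, not reads. The authors also deposited a log2 fold change, which equals the log2 ratio of the group means, and an unadjusted p-value per gene, computed from the same 4 columns. The m7G table deposited by the authors gives tRNA sequences, a position and a log2 ratio of cut quotients between a library pair. That ratio is set to 0 in 49 lines where the cut quotient of the first library is 0, so that no ratio can be formed. These lines were left out of medians, and their effect on the medians was not tested. Of its columns, 8 with values per library could not be matched to a sample and were not used, and 15 lines were not analysed here. The planned test of cleavage between the groups was therefore not made. One cleaved library labelled shGFP by its title and genotype has a description naming shMETTL1. It enters no comparison between groups, but the authors' ratios pool all library pairs and may include it.

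Groups were taken from the titles and genotypes. The design allowed for counts or normalized values. As the values are RPM, log2(RPM + 1) was tested with limma 3.58.1 (trend) in R 4.3.3, with group as the only term, no filter and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(RPM + 1) scale, which understates the change of low genes. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333. Isoacceptor sums add the RPM of all genes of an amino acid and anticodon. Met-CAT in the abundance table joins initiator and elongator tRNAs. Lists were tested with camera at a preset correlation of 0.01, adjusted over 4 lists, and again with an estimated correlation and with fry. No mitochondrial tRNA and no other small RNA was analysed here. Permutation tests of relations were two-sided with 100000 resamples. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

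The test was tried on simulated data with 536 genes, 60 of them changed in each of 20 runs. For the comparison of shMETTL1 with shGFP it recovered 26.1% of genes changed by 1 on the log2 scale, 73.0% of those changed by 2 and 86.3% of those changed by 3, and 3.82% of calls were false. The simulated noise was independent between genes and equally wide in both groups, and rises and falls were equally likely. The real data hold genes with identical values and a wider spread in shMETTL1, so these rates may not carry over to them. The depth behind low genes limits their precision, as 1 alignment was worth 0.120 and 0.128 RPM in shGFP and 0.294 and 0.217 RPM in shMETTL1. Over distinct profiles, the chi-square per degree of freedom between the libraries of a pair was 19.2 in shGFP and 1293 in shMETTL1. The values of a pair were not identical, and each library was counted as 1 replicate. Reads shared between near-identical copies enlarge these values, which do not show that the libraries came from separate cultures.

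The genes named were fixed by rule before the data were examined: the 10 largest falls and 10 largest rises past the threshold with groups that do not overlap, at most 3 copies per isoacceptor. Isoacceptors named were those of the motif list and the 10 most abundant others. Thr-AGT, Thr-TGT and Leu-TAA in the m7G table were named after their values were seen. Alternatives were median centring, scaling to the non-motif list, the upper 75% of genes by mean, pseudocounts of 0.1 and 10, a replicate block, an adjusted p of 0.1 and leaving out each library. Added after seeing the data were counting identical profiles once, leaving out glycine reads, and relating abundance to the authors' deposited ratio over all library pairs in place of the shGFP cleavage signal.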

Results

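LNZ308 is an established human glioblastoma cell line. METTL1 is the catalytic subunit of the methyltransferase that places 7-methylguanosine (m7G) in the variable loop of a subset of tRNAs, at position 46 of the standard tRNA numbering. Cells stably transduced with an shRNA against METTL1 were compared with cells carrying an shRNA against GFP, the control. The samples comprised 4 input libraries, 2 of shGFP and 2 of shMETTL1 cells, which measured tRNA abundance. They also comprised 3 libraries of chemically cleaved RNA, 2 labelled shGFP and 1 labelled shMETTL1, in which the RNA chain is cut at m7G. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. METTL1 mRNA was not analysed here, so the knockdown itself was not checked.

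The abundance table held 536 tRNA genes of 52 isoacceptors (tRNAs sharing an amino acid and an anticodon). Values were RPM, here counted alignments scaled to a common library total, and identical gene copies appear to be counted each time. The values of each library were whole multiples of 1 step, within a tolerance of 0.001. The steps correspond to 8307007 and 7792306 counted alignments in shGFP replicates 1 and 2, and to 3405840 and 4602187 in shMETTL1 replicates 1 and 2. The shGFP libraries resembled each other closely, with a standard deviation of their log2 differences of 0.172. In the shMETTL1 pair it was 0.799.

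The composition of the counted tRNA alignments differed between the groups and between the 2 shMETTL1 libraries. Glycine tRNAs made up 4.02% and 4.36% of RPM in the shGFP libraries, 29.8% in shMETTL1 replicate 1 and 7.39% in shMETTL1 replicate 2. Glutamine tRNAs made up 30.7% and 30.9% in shGFP, against 17.3% and 27.9% in shMETTL1 replicates 1 and 2. Methionine tRNAs made up 3.42% and 3.06% in shGFP and 0.584% and 1.40% in shMETTL1. Phenylalanine tRNAs made up 1.25% and 1.14% in shGFP and 0.209% and 0.386% in shMETTL1. RPM values are shares of a library, so a larger share of glycine tRNAs lowers the RPM of all other tRNAs. As identical copies appear to be counted each time, these shares also depend on the number of gene copies.

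**Figure D1:**
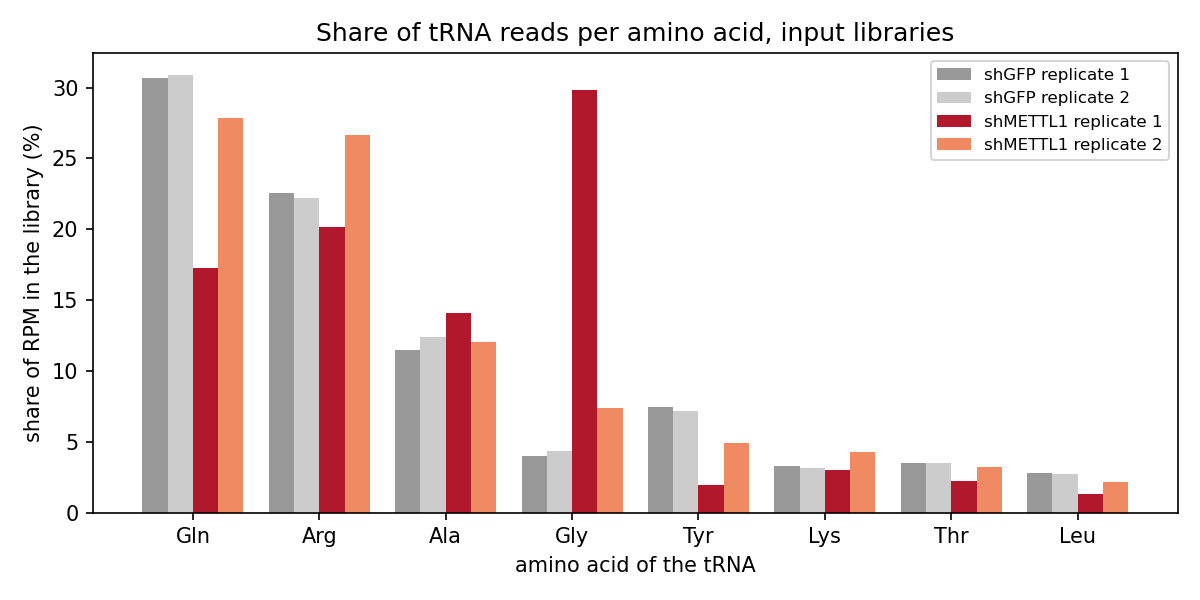
Share of RPM (%) taken by the tRNAs of the 8 most abundant amino acids in each of the 4 input libraries, 1 bar per library. Glycine tRNAs take 29.8% of shMETTL1 replicate 1, 7.39% of shMETTL1 replicate 2, and 4.02% and 4.36% of the shGFP libraries.

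The first comparison asked which tRNAs differ in abundance after METTL1 silencing. Single tRNA genes for valine, phenylalanine, isoleucine and methionine fell in shMETTL1 cells. The largest fall was at chr1.trna134-ValCAC, from 139.1 ± 29.9 RPM in shGFP to 15.8 ± 4.44 RPM in shMETTL1 (SD, n = 2 each; log2 change -3.07, SE 0.28, limma adjusted p = 0.0169). The gene chr6.trna157-ValCAC fell by 2.64 on the log2 scale (SE 0.30, limma adjusted p = 0.0197). Of the phenylalanine genes, chr6.trna108-PheGAA went from 1281 to 233 RPM (log2 change -2.60, SE 0.48). The near-identical chr6.trna111-PheGAA and chr11.trna14-PheGAA had log2 changes of -2.14 and -2.13. The isoleucine genes chr6.trna40-IleAAT, chr6.trna26-IleAAT and chr6.trna59-IleAAT had log2 changes of -2.23, -2.04 and -2.04. The methionine genes chr16.trna22-MetCAT and chr8.trna8-MetCAT had log2 changes of -2.04 and -2.03. The size of these falls depended on the shMETTL1 library. Without shMETTL1 replicate 1, chr1.trna134-ValCAC, chr6.trna108-PheGAA and chr6.trna40-IleAAT stood at -2.80, -1.94 and -1.61. Without shMETTL1 replicate 2 they stood at -3.35, -3.27 and -2.86.

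Of the 536 genes, 34 fell and 14 rose at a limma adjusted p of 0.05, and 99 and 105 were lower and higher at an unadjusted p under that value. The 34 genes belonged to 9 isoacceptors and held 26 distinct sets of values, because copies of a tRNA gene share reads. The genes that rose were of low abundance, with shGFP means of at most 42.9 RPM, and 7 of the 14 were Gln-TTG genes. The glutamine genes chr2.trna9-GlnTTG, chr2.trna21-GlnTTG and chrX.trna1-GlnTTG had log2 changes of 2.27, 2.24 and 2.23, from shGFP means of 2.41, 2.41 and 0.851 RPM. At such levels the size depends on the pseudocount: with 10 the values were 1.06, 1.03 and 0.67, and with 0.1 they were 2.63, 2.61 and 3.30. The sum of all Gln-TTG genes lay the other way, at 93826 RPM in shGFP and 68071 RPM in shMETTL1 (log2 change -0.51, SE 0.32, not past the threshold). It was at -0.15 without shMETTL1 replicate 1, -0.86 without shMETTL1 replicate 2 and -0.18 with median centring. This sum may share reads with Gln-CTG. The genes chr17.trna14-GlnTTG and chr15.trna8-GlnCTG, picked after their values were seen, stood at 18241 and 18211 RPM in shGFP replicate 1. In shMETTL1 replicate 1 they stood at 10217 and 10162 RPM. Of the genes that rose, chr5.trna24-AspGTC was the most abundant in shGFP and went from 42.9 ± 0.959 to 175.6 ± 29.5 RPM (SD, n = 2 each; log2 change 2.00, SE 0.23, limma adjusted p = 0.0197). The genes chrX.trna2-LeuTAA, chr1.trna124-GlyCCC and chr8.trna1-GluCTC had log2 changes of 1.82, 1.51 and 1.51. A gene on an unplaced contig, chr1_KI270713v1_random.trna2-AsnGTT, had a log2 change of 1.60. Low-abundance phenylalanine genes moved against the main copies: chr6.trna72-PheGAA rose from 41.0 to 116.2 RPM and chr6.trna90-PheGAA from 29.5 to 80.5 RPM.

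These counts depended on the scaling and on the genes tested. With log2 values centred on each library's median, 1 gene rose and 49 fell, and the median log2 change over all genes moved from -0.28 to 0.018. The rises did not shrink: chr2.trna9-GlnTTG stood at 2.56 and chr5.trna24-AspGTC at 2.29, with limma adjusted p of 0.132 and 0.0545. When libraries were scaled to the non-motif list, 0 genes passed in either direction by limma (93 higher and 85 lower at an unadjusted p under 0.05). The changes stayed close in size, at -3.12 for chr1.trna134-ValCAC (limma adjusted p = 0.0532), -2.66 for chr6.trna108-PheGAA and 2.22 for chr2.trna9-GlnTTG. With the main scaling, in the upper 75% of genes by mean 1 rose (chr5.trna24-AspGTC) and 2 fell (chr1.trna134-ValCAC and chr6.trna157-ValCAC). The filter leaves the log2 changes as they were: chr6.trna108-PheGAA stayed at -2.60 and chr6.trna40-IleAAT at -2.23, each at a limma adjusted p of 0.0618. Without shMETTL1 replicate 1 the counts were 161 and 163, without shMETTL1 replicate 2 they were 163 and 281, without shGFP replicate 1 they were 9 and 21, and without shGFP replicate 2 they were 8 and 16, higher and lower respectively. In 175 genes both shMETTL1 values lay above both shGFP values, and in 229 both lay below, together 75.4% of genes. For a single gene the chance of this is 33.3%. Genes share reads and a library total and so move together, and the 75.4% is therefore not a test against that value. In the authors' deposited table, 82 genes were lower and 48 higher at the authors' unadjusted p under 0.05.

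Summed per isoacceptor, Phe-GAA, Ile-TAT, Met-CAT and Trp-CCA had the lowest values in shMETTL1 relative to shGFP among the isoacceptors of the motif list. Phe-GAA stood at 11946 ± 837 RPM in shGFP and 2974 ± 1254 RPM in shMETTL1 (SD, n = 2 each). On the mean of log2(RPM + 1) it was 4.20-fold lower (log2 change -2.07, SE 0.35, limma adjusted p = 0.0860). The log2 changes of Ile-TAT, Met-CAT and Trp-CCA were -1.98 (SE 0.46), -1.84 (SE 0.47) and -1.76 (SE 0.46), each at the same adjusted p. The valine isoacceptors Val-CAC, Val-AAC and Val-TAC had log2 changes of -1.15 (SE 0.24), -1.10 (SE 0.25) and -0.85 (SE 0.38). Tyr-GTA had a log2 change of -1.23 (SE 0.50) and Ile-AAT of -0.68 (SE 0.28). Each of these 9 isoacceptors was lower in both shMETTL1 libraries than in both shGFP libraries, and none changed direction with either scaling. Such separation was common: of all 52 isoacceptors, 25 lay lower in both shMETTL1 libraries and 17 higher. The sizes depended on the shMETTL1 libraries. Without shMETTL1 replicate 1, the log2 changes of Met-CAT, Trp-CCA, Tyr-GTA, Val-TAC and Ile-AAT were -1.21, -1.15, -0.56, -0.38 and -0.36, and without shMETTL1 replicate 2 they were -2.47, -2.38, -1.90, -1.31 and -0.99. Ile-AAT had a log2 change of -1.18 with identical profiles counted once.

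Of the isoacceptors with higher values, Gly-GCC went from 28857 ± 1980 to 139372 ± 121738 RPM (SD, n = 2 each; log2 change 1.93, SE 0.75) and Gly-CCC from 10699 ± 544 to 44850 ± 37047 RPM (log2 change 1.77, SE 0.69). Their limma adjusted p was 0.167. Without shMETTL1 replicate 1 their values were 0.89 and 0.80, and without shMETTL1 replicate 2 they were 2.97 and 2.73. The Gly-GCC and Gly-CCC sums may not be separate results. In shMETTL1 replicate 1 a Gly-CCC gene stood at 16096 RPM and a Gly-GCC gene at 16036 RPM, with near-equal values in the other libraries. A Glu-TTC gene stood at 15184 RPM there and another Gly-CCC gene at 15168 RPM. Reads therefore appear to be shared across anticodons and amino acids as well as between copies. Arg-TCT, which carries the variable-loop motif, had a log2 change of 1.16 (SE 0.50), Cys-GCA of 0.51 (SE 0.25) and Lys-CTT of 0.42 (SE 0.21). Without shMETTL1 replicate 1 these were 0.50, 0.29 and 0.26, and without shMETTL1 replicate 2 they were 1.81, 0.73 and 0.59. Ala-AGC, Ala-TGC, Ala-CGC and Lys-TTT had values of 0.08, 0.15, 0.16 and 0.10, which turned negative when libraries were scaled to the non-motif list. With median centring they were 0.41, 0.47, 0.49 and 0.43. The alanine sums may share reads too, as an Ala-CGC gene and an Ala-TGC gene stood at 7639 and 7638 RPM in shGFP replicate 1. Lys-TTT was at 0.44 without shMETTL1 replicate 1 and -0.24 without shMETTL1 replicate 2. The 3 alanine values lay between 0.010 and 0.017 without shMETTL1 replicate 1 and between 0.15 and 0.30 without shMETTL1 replicate 2. Asn-GTT had a value of -0.25, which turned positive with median centring (0.076) and without shMETTL1 replicate 1 (0.046), and was -0.55 without shMETTL1 replicate 2. The isoacceptors with the highest summed RPM in shGFP, Gln-CTG and Arg-ACG, had log2 changes of -0.48 (SE 0.35) and -0.03 (SE 0.32). Their RPM is enlarged by identical copies, but with identical profiles counted once the changes were -0.50 and -0.03. Gln-CTG was at -0.14 without shMETTL1 replicate 1, -0.83 without shMETTL1 replicate 2 and -0.15 with median centring. The Gln-CTG and Gln-TTG sums may not be separate results, as abundant genes of both had near-equal values in each library. Arg-ACG was at 0.23 without shMETTL1 replicate 1, -0.29 without shMETTL1 replicate 2 and 0.30 with median centring, so its direction was not settled. Pro-CGG and Pro-TGG stood at 0.622 and 2.17 RPM in shGFP, too low for a reading of their change.

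No isoacceptor sum passed a limma adjusted p of 0.05 (0 of 52). At an unadjusted p under that value, 9 were lower and 4 higher, and with median centring 8 were lower and 15 higher. The count past the adjusted threshold depended on the shMETTL1 libraries: 21 were higher and 22 lower without shMETTL1 replicate 1, and 19 higher and 31 lower without shMETTL1 replicate 2. With glycine reads left out, an alternative chosen after seeing the data, 8 were lower and 3 higher past that threshold. Those lower included Phe-GAA, Ile-TAT, Met-CAT, Trp-CCA, Val-CAC and Val-AAC, with limma adjusted p from 0.0186 for Phe-GAA to 0.0394 for Val-AAC. These 6 are of the motif list, and the others that were lower lay outside it. Those higher included Pro-CGG, at 0.622 RPM in shGFP too low for a reading.

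**Figure D2:**
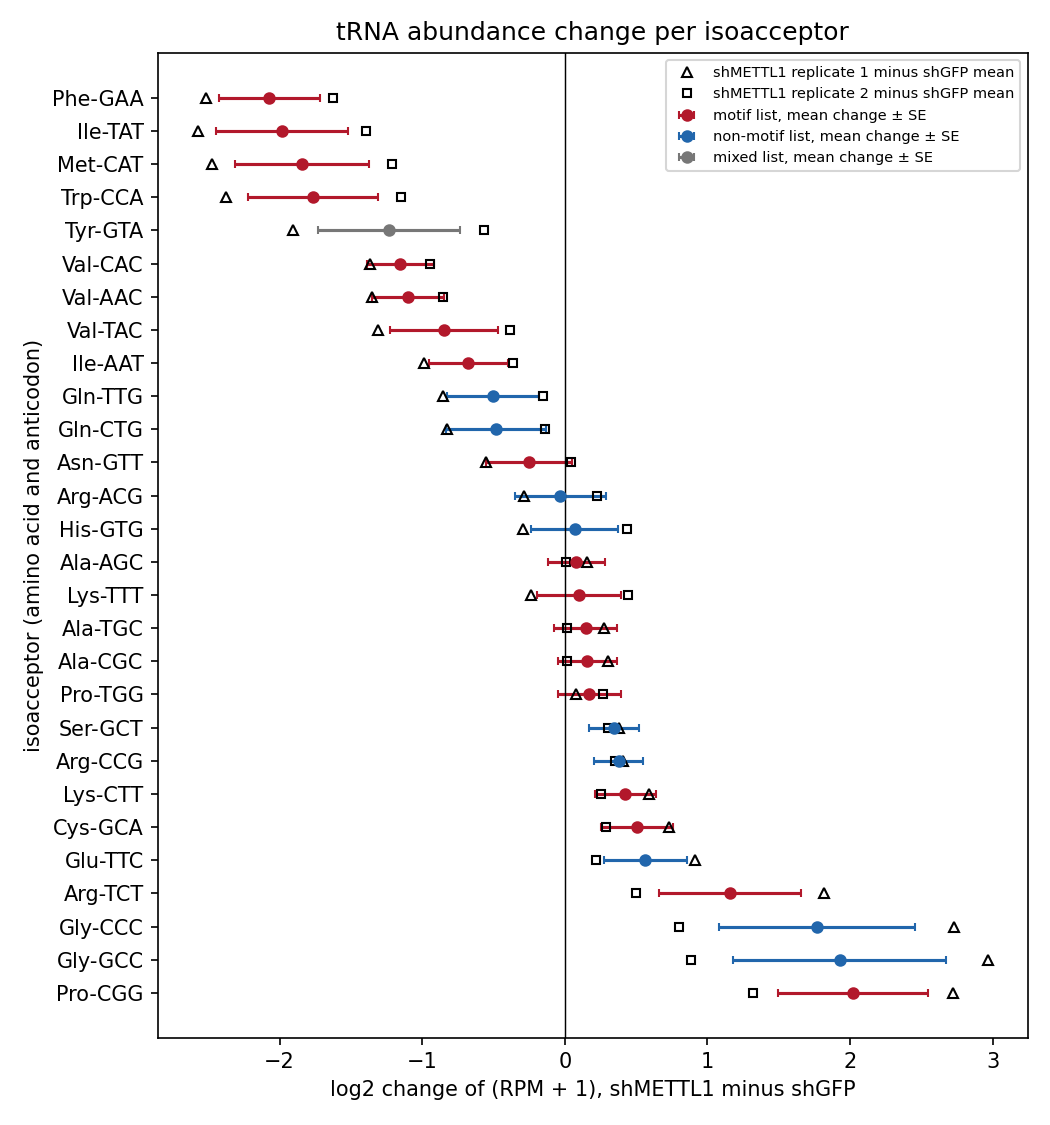
Log2 change of RPM + 1 (shMETTL1 minus shGFP, x axis) for each isoacceptor of the motif list and the 10 most abundant others (y axis). Filled points with bars are the limma estimate ± SE (n = 2 each), coloured by list, and open triangles and squares are shMETTL1 replicates 1 and 2 against the shGFP mean. Phe-GAA lies at -2.07 and Gly-GCC at 1.93, and in both the open triangle lies farther from 0 than the open square.

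The isoacceptors were then grouped by lists fixed before the data were examined. The motif list holds isoacceptors known to carry a purine-A-G-G-U or similar motif in the variable loop. Of its 261 genes, of 18 isoacceptors, 32 fell, 3 rose and 226 did not pass, and 74 fell and 6 rose when adjusted over the list alone. The genes that fell included chr1.trna134-ValCAC, chr6.trna108-PheGAA and chr6.trna40-IleAAT, and those that rose were chr6.trna72-PheGAA, chr6.trna90-PheGAA and chr1_KI270713v1_random.trna2-AsnGTT. The median log2 change of the list was -0.28 and its mean -0.40, against a median of -0.28 over all genes, and camera placed it below other genes (adjusted p = 0.00449, preset correlation 0.01). With an estimated correlation the call was lost (adjusted p = 0.528). The median was -0.034 without shMETTL1 replicate 1, -0.58 without shMETTL1 replicate 2 and 0.0081 with median centring. Of the list's 18 isoacceptors, 9 had a log2 change below 0 and 9 above, the latter including Pro-CGG and Pro-TGG at very low RPM. With median centring 8 lay below and 10 above, and with scaling to the non-motif list 14 lay below and 4 above.

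The non-motif list, which includes the glycine, glutamine and aspartate isoacceptors, held 217 genes, of which 11 rose, 2 fell and 204 did not pass. When adjusted over the list alone, 9 rose and 2 fell. Of the 11 that rose, 7 were Gln-TTG genes, although the Gln-TTG sum had a log2 change of -0.51. The list's median log2 change was 0.071 and camera placed it above other genes (adjusted p = 5.04e-04), a call lost with an estimated correlation (adjusted p = 0.528). The median over its isoacceptor sums had the opposite sign, -0.18, as did the median over genes without shMETTL1 replicate 2, -0.29, while without shMETTL1 replicate 1 it was 0.28. The list holds the glycine tRNAs, whose share in shMETTL1 replicate 1 was 29.8%. With glycine reads left out the median was 0.20 and the call stood at the preset correlation (camera adjusted p = 0.00349). Of the 71 genes with a long variable arm, those of leucine, serine and selenocysteine, chrX.trna2-LeuTAA rose, and chr6.trna42-SerACT and chr11.trna1-LeuCAA, named after their values were seen, fell, and 0 passed when adjusted over the list alone (0 higher, 0 lower by limma). Their median was -0.50 (camera adjusted p = 0.00449, or adjusted p = 0.528 with an estimated correlation). It was -0.32 without shMETTL1 replicate 1 and -0.79 without shMETTL1 replicate 2. With glycine reads left out it was -0.25 and the call was lost (camera adjusted p = 0.0508). Of the 48 threonine and tyrosine genes of the mixed list, 0 passed by limma, also over the list alone, and the median was -0.30 (camera adjusted p = 0.156, or adjusted p = 0.571 with an estimated correlation).

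The cleaved libraries were made to locate m7G. In the authors' deposited table of m7G sites, 145 sites lay in 132 tRNA sequences of 24 isoacceptor types. Counted from the 5′ end of the tRNA, the listed position was 46 in 59 sites, 47 in 59, 48 in 18 and 45 in 9. These are counts along each sequence, not standard tRNA numbers, so a 46 here does not mark a match to position 46. Counted from the 3′ end with the CCA tail, it was 30 in 125 of 145 sites (86.2%). The base before the listed position was G in 145 of 145 sites. The 5 bases up to and with the position were GAGGT in 46 sites and AAGGT in 39, together 85 sites (58.6%) with a purine before AGGT. In these 85 sites the listed base is the T, which cannot itself be m7G, and the base before it is a G. Other sequences included AGGGT in 12 sites (5 of Lys-CTT, 6 of Lys-TTT and 1 of Thr-TGT), GAGGC in 10 and TAGGT in 9 sites of tyrosine tRNAs.

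The authors' deposited table gives at each site a log2 ratio between the cut quotients of 2 libraries, the second of a pair over the first. The names of its 3 library pairs match no sample label, so no shMETTL1 against shGFP comparison of cleavage was made, and which library of a pair was the input is not stated there. Over 340 lines with a ratio in the authors' deposited table, the median log2 ratio was 3.03, with a range of 0.027 to 7.58. In the authors' deposited table the median was 3.70 over 193 lines with a purine before AGGT and 2.03 over 147 other lines, a difference that was not tested. In that direction, second over first, the highest medians in the authors' deposited table were those of elongator Met-CAT (5.49), Val-AAC (5.36) and Val-CAC (5.24). The lowest in the authors' deposited table were Tyr-GTA (1.42), Thr-AGT (1.38) and Leu-TAA (1.29). Lines with a ratio there were 9 of 11 for elongator Met-CAT, 6 of 8 for Val-AAC and 10 of 15 for Val-CAC. For Tyr-GTA, Thr-AGT and Leu-TAA they were 39 of 40, 7 of 7 and 8 of 8. The order of the medians may therefore depend on the lines left out. It may also depend on where the sites lie. Counted from the 3′ end, the Thr-AGT sites lay at 33 and the Leu-TAA sites at 40 or 41, against 30 in 125 of 145 sites. Of the 14 Tyr-GTA sites, 5 lay at 31, next to another listed site of the same tRNA. The effect on these medians was not tested. Initiator methionine tRNA, which starts protein synthesis, had a median of 2.73 in the authors' deposited table.

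**Figure D3:**
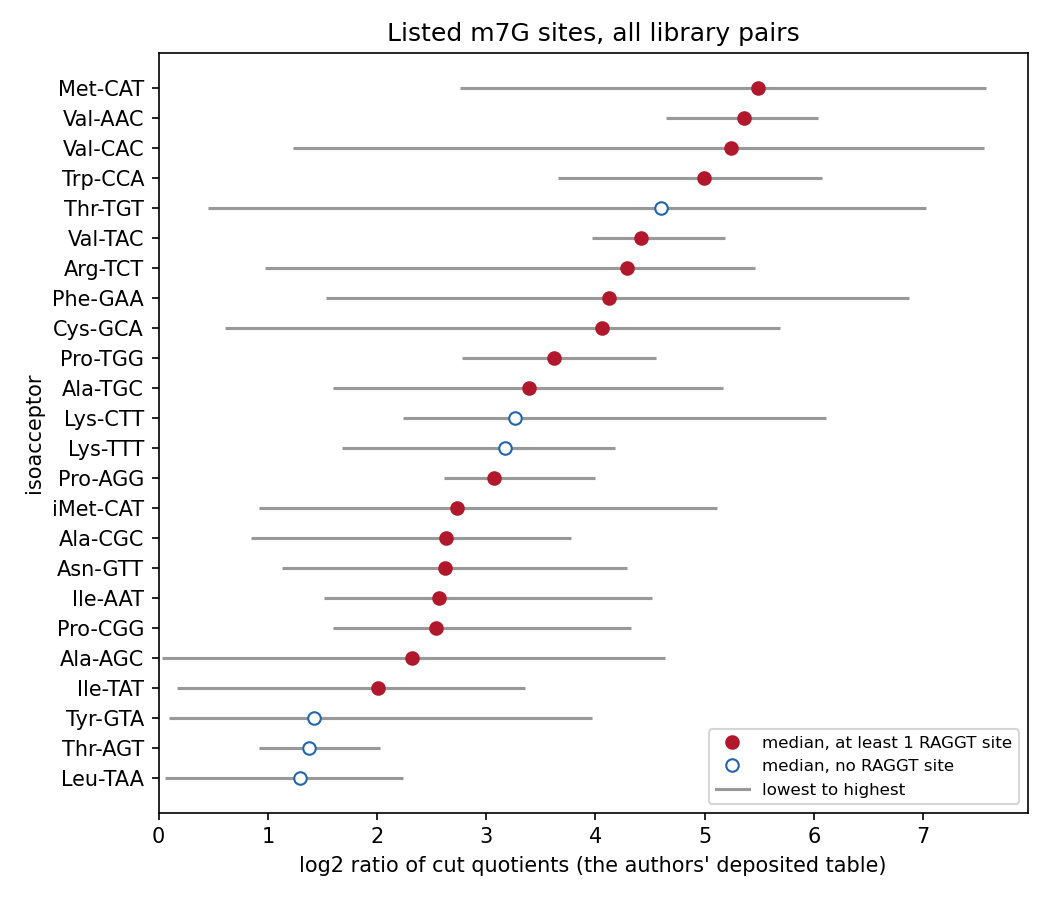
Log2 ratio of cut quotients at listed m7G sites (x axis) for 24 isoacceptor types (y axis), from the authors' deposited table, over all library pairs. Points are medians, filled where at least 1 site has a purine before AGGT, and lines run from the lowest to the highest value; Met-CAT has the highest median, 5.49, and Leu-TAA the lowest, 1.29.

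Abundance and the listed sites were compared by isoacceptor. The 310 genes of the 22 isoacceptors with a listed site had a median log2 change of -0.29, against 0.020 for the other genes, and 32 of them fell and 4 rose. Camera placed them below the other genes (p = 4.74e-05), a call lost with an estimated correlation (p = 0.249) and on isoacceptor sums (camera p = 0.121). The 219 genes of 16 isoacceptors with a listed purine before AGGT had a median of -0.39, against 0.050 for the rest, and 32 fell and 3 rose. Camera placed these below the rest (p = 6.41e-06), a call also lost with an estimated correlation (p = 0.223) and on isoacceptor sums (camera p = 0.262). The 22 isoacceptors are the motif list with Tyr-GTA, Thr-AGT, Thr-TGT and Leu-TAA added. The 16 are the motif list without Lys-CTT and Lys-TTT. These camera tests therefore largely repeat that of the motif list on the same genes, and their p-values were not adjusted. Across the 22 isoacceptors with a listed site, the median ratio in the authors' deposited table showed no detectable relation to the abundance change (Spearman's rho -0.11, permutation p = 0.620; Pearson's r -0.14, permutation p = 0.530; adjusted p = 0.620 for both over 4 relations computed). The ratio pools all library pairs and leaves out lines where it is 0, and isoacceptors are not independent replicates. The 22 include Pro-CGG and Pro-TGG, whose RPM was too low for a reading of their change. They also include Thr-AGT and Leu-TAA, which have no listed site at 30 from the 3′ end.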

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

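Counting identical profiles once, leaving out glycine reads and using the authors' deposited ratio were chosen after seeing the data; all other alternatives were planned. The main counts were 14 genes higher and 34 lower, and 0 isoacceptor sums. Counts of genes within 1.5-fold of these came with pseudocounts of 0.1 (15 and 39) and 10 (10 and 32) and with identical profiles counted once (12 and 23). Median centring gave 1 higher and 49 lower, a share of higher calls of 2% against 29.2%, and kept 32 of the 48 genes called. Scaling to the non-motif list gave 0 and 0 by limma (93 and 85 at an unadjusted p under 0.05). The upper 75% of genes by mean gave 1 and 2 with fewer genes tested. An adjusted p of 0.1 gave 79 and 84. Leaving out glycine reads gave 69 and 92, and kept 47 of the 48. Leaving out each library in turn gave 8 to 163 higher and 16 to 281 lower. The highest counts came without a shMETTL1 library, where the lone library is assumed to vary like the shGFP pair. Except where a cause is named, the cause was not tested.

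Replicate numbers are shared between the groups, but 2 pairs do not show that they pair the libraries, and the deviations of same-numbered libraries had a correlation of -0.028. With the replicate block, 63 genes were higher and 70 lower, and 1 isoacceptor was higher and 3 lower. Isoacceptor sums gave 3 higher and 8 lower with glycine reads left out, and 0 to 21 higher and 0 to 31 lower when each library was left out in turn.

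The directions of the 20 named genes held under every alternative that tested them. Most alternatives could not have reversed them, as the genes were picked with groups that do not overlap. Only median centring, scaling to the non-motif list and leaving out glycine reads could have done so. All 20 lost the threshold when scaled to the non-motif list, and 9 did with median centring. In the upper 75% of genes by mean 10 lost it, with identical profiles counted once 4, and with a pseudocount of 10, 3. With glycine reads left out, the 19 genes tested stayed past it. At an adjusted p of 0.1 no gene could lose it. The camera calls were lost with an estimated correlation for the motif list (median log2 change -0.28), the non-motif list (0.071) and the long variable arm (-0.50). Fry, which asks whether a list moves one way and compares it with no other genes, gave an adjusted p of 0.215 for each of these. Leaving out each library gave medians of -0.58 to -0.034 for the motif list and -0.29 to 0.28 for the non-motif list, with camera calls in the main direction. With isoacceptor sums they were lost too, at medians of -0.085, -0.18 and -0.51. The motif list was also lost with identical profiles counted once (-0.024, adjusted p = 0.126). The long variable arm was lost with glycine reads left out (-0.25), and its median lay between -0.79 and -0.32 with each library left out, lost in 3 of 4. With each library left out the mixed list lay between -0.47 and -0.21 and was called only without shMETTL1 replicate 2. The relation of abundance to the authors' deposited ratio stayed negative and did not pass with Pearson's r (-0.14) or in the motif list alone (rho -0.29, adjusted p = 0.495).

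Not run were all alternatives for cleavage between groups and the relation over single tRNAs, since library pairs could not be assigned, and those for count tables. As deposited without centring and without a filter are the main settings.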

Other observations

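The tests below were chosen after the results were seen. For the relation between the authors' deposited ratio and the fall in abundance, the measure was chosen after seeing the data and the bounds were written before the coefficient was computed, but its interval was added after it was seen. The threonine tRNA Thr-TGT, named after its value was seen, had a median log2 ratio of 4.60 in the authors' deposited table with no purine before AGGT at any of its 7 sites, and 4 of these held GGGGTCG. Cysteine tRNA Cys-GCA had the most listed sites, 20, and a median ratio of 4.06 in the authors' deposited table, while its abundance had a log2 change of 0.51. The serine tRNA Ser-ACT and the leucine tRNA Leu-TAA, both named after their values were seen, had abundance log2 changes of -1.94 (SE 0.38) and -1.46 (SE 0.39), neither past the limma adjusted threshold among the 52 sums (0.0860 for both). Ser-ACT has 1 gene, and the same values passed among the 536 single genes (SE 0.32, limma adjusted p = 0.0326), since the 2 fits estimate the spread from different sets.

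Phe-GAA, Met-CAT, Trp-CCA, Ile-TAT and the 3 valine isoacceptors had a median log2 change of -1.76. With glycine reads left out of each total the median was -1.52, with a range of -1.82 to -0.60, which argues against the glycine share as the whole cause. In shMETTL1 replicate 2 the median was -1.15, against -2.38 in replicate 1 and a largest shGFP range of 0.159, so the fall was present in both libraries. As these isoacceptors were picked for falls in the same values, this is no independent test of 1 outlying library. Loss of m7G in the knockdown may be an explanation. Falls of this size also occurred without a listed m7G site. Ser-ACT, with 1 gene, had a log2 change of -1.94 and Tyr-ATA, named after its value was seen, of -1.56. Of the 30 isoacceptors without a listed site, 15 lay below 0. A difference between stable clones stays open, as the design confounds it with the group, and so does a change in how well these tRNAs are reverse transcribed.

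Isoacceptors with listed m7G sites had values on both sides of 0. In the most abundant gene of each of 8 such isoacceptors with no large fall, of alanine, arginine, asparagine, cysteine and lysine, the median log2 change was 0.157, with a range of -0.28 to 1.43. These values lay within 0.271 of the isoacceptor sums and carry the same shared reads, so they do not decide whether reads shared between copies hide falls, and that stays open. Whether a larger authors' deposited ratio goes with a larger fall remained undecided. Spearman's coefficient was -0.11, above the bound of -0.2 written beforehand as speaking against it, but not by more than its spread, as the 95% bootstrap interval of -0.53 to 0.40 holds that bound and the opposite bound of -0.4. The few isoacceptors and the pooling of library pairs keep it open.

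Replicate 1 of shMETTL1 differed more from shGFP than replicate 2. Across isoacceptors, the changes of the 2 libraries, each against a separate shGFP library, had a Pearson's r of 0.894 and a slope of 0.44, and with the controls exchanged r was 0.912. In 42 of 52 isoacceptors replicate 2 lay between shGFP and replicate 1. This is consistent with 1 profile of change at 2 strengths, which may reflect the degree of knockdown or of RNA quality; neither was tested. Lower depth does not account for it, as the 20 isoacceptors with a shGFP mean of at least 10000 RPM differed between the 2 libraries by a median of 0.698 on the log2 scale, against 0.064 in shGFP.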
